A study of Mus musculus with 12 samples.

How the data were processed

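Whole lungs of mice were profiled 3 days after intranasal infection with the intracellular bacterium Chlamydia pneumoniae or after mock infection. Wild-type C57BL/6 mice and mice lacking Myd88, the adaptor protein through which most Toll-like receptors and the interleukin-1 receptor signal, gave 4 groups of 3 arrays. Per the labels' protocols, the inoculum was given in 30 microlitres, blood was flushed out of the lungs through the heart before freezing, and total RNA was amplified in a single round and biotin-labelled. The design text describes the replicates as single mice from 3 independent infection experiments, and the replicates carry the letters A, B and C in every group. One array, wild-type infected C, carries a knockout entry among its characteristics, while its title, source name and description all call it wild type. It was grouped by its title, and the tests of genes and lists were also run without it.

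The deposited values are linear intensity values, 1 per probe set, made by the authors with RMA from the affy package in R 2.4.0 per the submitters' processing notes, with no settings given in the sources used here. RMA as published corrects the background, normalizes by quantiles and summarises the probes of a set. The design fixed before the data were examined had assumed log2 values; the values run from 14.2 to 25972, so log2 was taken here, with no pseudocount since no value was at or below 0. Array medians lay between 317 and 329, so the values had been brought to a common scale. No value was missing, and no pair of arrays was identical. With 3 arrays per group, the standard error of a log2 difference between groups was 0.18 for Myd88.

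The table holds 22690 probe sets. Of these, 64 are hybridisation and RNA controls and were left out of the tests. Through the platform annotation, 20380 probe sets have 1 gene symbol, 691 have several and 1555 have none; only those with 1 symbol named a gene. No symbol had to be updated through its gene identifier. For each of the 12393 genes, the probe set with the highest mean over the 12 arrays stood for the gene; 4956 genes had more than 1 probe set. Where another probe set of a named gene had the opposite sign, it did not pass the threshold in the test of every probe set.

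Differences were tested with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group was fitted to all 12 arrays, so that the groups shared an estimate of the spread with 8 residual degrees of freedom, followed by empirical Bayes moderation without trend or robust options. Benjamini-Hochberg adjustment ran over the 12393 genes within each comparison, and a gene was called at an adjusted p below 0.05. The 5 comparisons were infection in wild type, infection in the knockout, the difference between these responses (the interaction), genotype in mock-infected mice and genotype in infected mice. Errors beside log2 differences are standard errors of that model, and levels are mean log2 intensities with their SD. Lists of genes, 30 in all, were fixed before the data were examined, together with the designs, the alternatives and the rule for named genes. The lists covered inflammatory and interferon genes, antigen presentation, markers of lung and blood cell types, muscle, fat, proliferation, stress, clock and xenobiotic genes, and neighbours of Myd88 on its chromosome. They held 590 entries, 100 of which were not measured. Some genes are on several lists, such as Itgam (neutrophil and monocyte lists) and Lcn2 (neutrophil and acute phase lists). Calls of lists that share genes are therefore not independent of each other. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 150 tests of 30 lists in 5 comparisons. Camera was run again with the correlation estimated from the data.

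Named genes followed this rule: per comparison the 15 largest rises and 10 largest falls among called genes whose groups did not overlap (a condition not set for the interaction), up to 4 called members and up to 2 members not called per list, and a fixed set of 18 genes of innate immunity and lung epithelium; the text names some of these. Genes named outside the rule are marked as chosen after their values were seen.

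The method was tested on simulated data made from the real gene means and residual spreads, with 200 of the 12393 genes changed in the wild-type infected group. For infection in wild type, 80% of changes of 1 log2 unit and 100% of changes of 2 units were recovered with the right sign, and 9 unchanged genes were called. For the interaction the shares were 57% and 97%, with 6 unchanged genes called, and for genotype in infected mice 85% and 98%, with 9. Of 100 random lists, 1 had an unadjusted camera p below 0.05 for infection in wild type and 5 for infection in the knockout. Each gene on each array was drawn independently in this simulation. It therefore does not show how often camera calls lists of correlated genes by chance, or what deviations shared between arrays do.

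Whether the letters pair arrays was checked from the correlation across genes of same-letter deviations from the group means. The correlations for A, B and C were 0.158, 0.364 and 0.119 between the wild-type groups, 0.350, 0.538 and 0.434 between the knockout groups, 0.460, 0.396 and 0.771 between the mock groups, and 0.0469, 0.0910 and 0.219 between the infected groups. Each of the 12 arrays correlated best with an array of its own letter. The letters were therefore taken to pair arrays in every comparison except genotype in infected mice, and the fit was repeated with the letter as a block. Camera with an estimated correlation was run without this block only, so deviations shared within a letter enter that estimate. Xist was at 458 to 558 on the A arrays and at 4186 to 6942 on the B and C arrays, and the Y-linked Eif2s3y was at 140 to 284 on the A arrays and at 17.2 to 19.9 on the others. Sex therefore follows the letter alike in all 4 groups (both genes were chosen after their values were seen). When an A array is left out, its group keeps only B and C arrays, so sex then differs between the groups. The fits that leave out an array had no block.

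Alternatives were a filter on dim genes, every probe set on its own, the mean over a gene's probe sets, median centring, cyclic loess, trend and robust moderation, array weights, fitting only the groups compared, the letter as a fixed or a random block, a fold minimum of 1 log2 unit, each of the 12 arrays left out in turn and, for lists, an estimated correlation and ranks. After seeing the data, 3 settings were added that leave out the mock C arrays of both genotypes, the knockout B arrays, or knockout infected C with both mock C arrays. Figures were drawn with matplotlib.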

Results

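The data are RMA intensities of 22690 probe sets on each of 12 arrays, from whole lung taken 3 days after intranasal Chlamydia pneumoniae or mock infection. Wild-type and MyD88 knockout mice gave 3 arrays per group, and within groups the arrays correlated at r = 0.966 to 0.994 across genes. The series asks which parts of the lung's transcriptional response to this infection need MyD88.

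The targeted gene was read first. Myd88 is measured by a single probe set, and its intensity was 1016, 1099 and 1014 in the wild-type mock lungs A, B and C, and 1228, 862 and 1156 in the knockout mock lungs. After infection it was 2257, 2289 and 1573 in wild type and 1318, 923 and 1106 in the knockout. Genotype made no called difference in mock-infected mice (log2 difference 0.04 ± 0.18, adjusted p = 0.980). Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so this signal neither checks nor contradicts the genotype labels. Myd88 signal rose with infection in wild type (log2 fold change 0.95 ± 0.18, adjusted p = 0.00699) and was 0.05 ± 0.18 in the knockout, and the difference between these responses did not pass (adjusted p = 0.344). In infected mice it was lower in the knockout (-0.86 ± 0.18, adjusted p = 0.0298), a call lost without wild-type infected A or B or knockout infected B or C (highest adjusted p = 0.178).

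**Figure D1:**
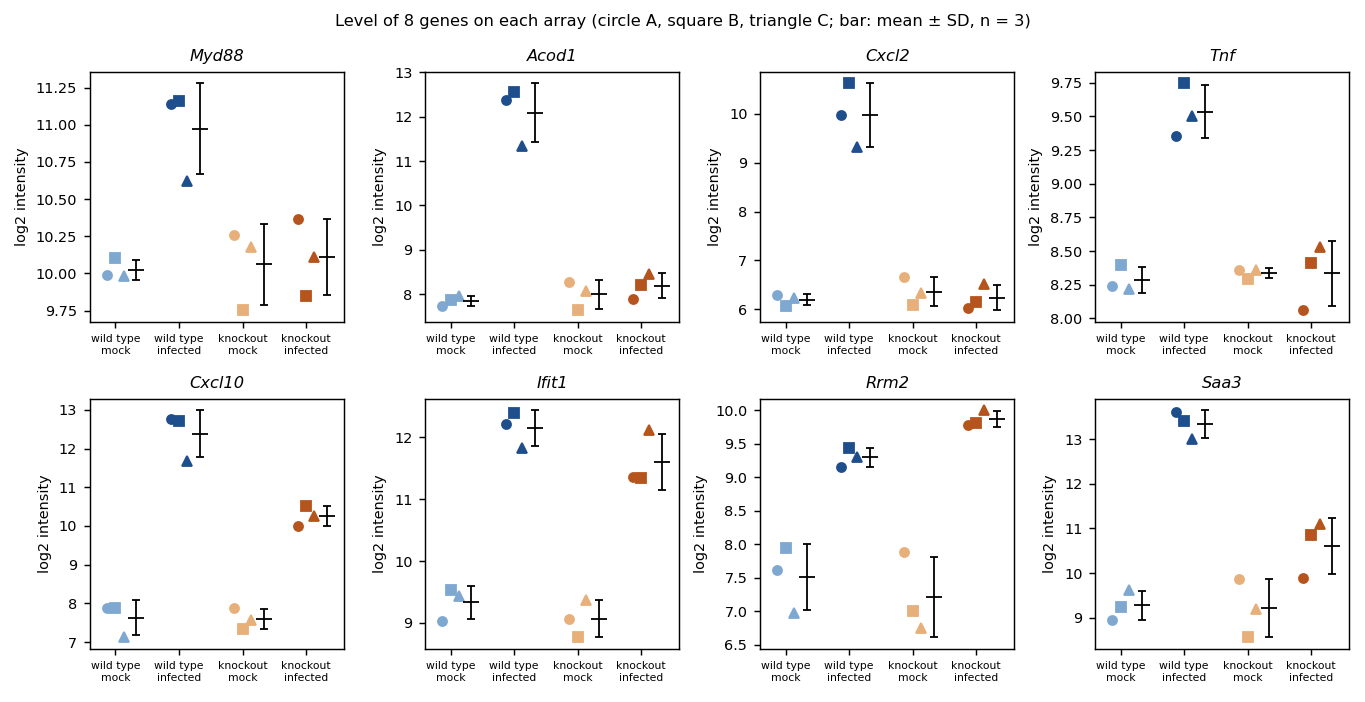
Log2 intensity of 8 genes on each array (vertical axis) in the 4 groups (horizontal axis). Circles, squares and triangles are replicates A, B and C, and bars give the mean ± SD of 3 arrays. The 3 wild-type infected arrays lie above all other arrays for Acod1, Cxcl2, Tnf, Cxcl10 and Saa3, and both infected groups lie above both mock groups for Ifit1 and Rrm2.

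Infection of wild-type mice raised chemokines, acute phase proteins and interferon-stimulated genes in the lung by up to 27-fold. The T-cell-attracting chemokine Cxcl10 rose most, by a log2 fold change of 4.75 ± 0.29 (n = 3 against 3), followed by Acod1, the enzyme that makes itaconate in macrophages (4.24 ± 0.27), the chemokine Ccl3 (4.11 ± 0.18) and the acute phase protein Saa3 (4.07 ± 0.34). In all, 543 genes were higher and 323 lower among 12393, and 258 of the rises but only 31 of the falls reached 1 log2 unit. The falls included the growth factor binding proteins Igfbp3 (-1.72 ± 0.25) and Igfbp6 (-1.40 ± 0.23), the serine protease Prss23 (-1.28 ± 0.26), and enzymes of xenobiotic metabolism.

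Chemokines and cytokines rose as groups in wild type. Among neutrophil-attracting chemokines and colony-stimulating factors, 5 of 10 measured members were called higher (5 adjusted over the list alone), among them Ccl3, Cxcl2 (3.77 ± 0.26), Ccl4 (2.56 ± 0.23) and Cxcl1 (1.75 ± 0.20). Of 17 chemokines for monocytes and lymphocytes 9 rose (11 adjusted over the list alone), including Cxcl9 (3.22 ± 0.27), the monocyte attractants Ccl2 (3.20 ± 0.31) and Ccl12 (3.15 ± 0.25), and Ccl7 (2.39 ± 0.23). Proinflammatory cytokines and NF-kB targets had 19 of 29 members higher and a median log2 fold change of 0.82 (22 adjusted over the list alone). Il1rn, the interleukin-1 receptor antagonist, rose by 3.00 ± 0.24, Il1b by 2.46 ± 0.25, Il6 by 2.18 ± 0.36 and Tnf by 1.25 ± 0.14. Il12b (0.21 ± 0.10, adjusted p = 0.296) and Ifng (0.53 ± 0.17, adjusted p = 0.0858, and 0.0432 without knockout infected C) did not pass.

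Interferon-responsive genes rose as well. All 30 measured type I interferon-stimulated genes rose, with a median of 1.64 (30 adjusted over the list alone); Rsad2 and Mx1, both antiviral effectors, rose by 3.38 ± 0.35 and 3.38 ± 0.36, Ifit2 by 2.95 ± 0.21 and Oasl2 by 2.48 ± 0.20. Interferon-gamma-inducible genes had 18 of 24 members higher, with a median of 1.54 (21 adjusted over the list alone). They included the Fc receptor Fcgr1 (3.25 ± 0.27) and the GTPase Irgm1 (1.73 ± 0.15). In MHC class I presentation 5 of 12 members rose (9 adjusted over the list alone), led by the peptide transporter Tap1 (1.51 ± 0.22). The list call was lost with an estimated correlation (adjusted p = 0.212). The class II list was not called, with adjusted p = 0.120 and a median of 0.42.

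Markers of myeloid cells were higher in infected wild-type lungs. Neutrophil markers had 10 of 22 members higher (16 adjusted over the list alone), among them the lectin receptors Clec4e (3.43 ± 0.21) and Clec4d (2.57 ± 0.14), the integrin Itgam (1.91 ± 0.26) and Lcn2 (1.98 ± 0.28), while S100a8 varied between arrays (2.07 ± 0.85, adjusted p = 0.186, and 0.00263 with the replicate block). Monocyte and macrophage markers had 12 of 19 higher (12 adjusted over the list alone; adjusted p = 0.0557 with an estimated correlation), such as Ms4a6d (3.46 ± 0.31), Clec4a2 (1.91 ± 0.15) and Adgre1 (1.66 ± 0.14). Another Ms4a6d probe set had the opposite sign and did not pass. Complement genes (7 of 13 higher, and 7 adjusted over the list alone, with adjusted p = 0.0880 with an estimated correlation) included the receptor C3ar1 (2.36 ± 0.13) and factor B, Cfb (2.37 ± 0.22). Acute phase and antimicrobial genes (11 of 26 higher, and 15 higher and 2 lower adjusted over the list alone) included Serpina3n (1.89 ± 0.24) and Orm1 (1.66 ± 0.23). In the Toll-like receptor pathway 4 of 16 rose (10 adjusted over the list alone, with adjusted p = 0.0557 with an estimated correlation), with Cd14 at 1.75 ± 0.22, Tlr1 at 1.74 ± 0.23 and Tlr2 at 1.72 ± 0.24; Tlr4 was at 0.45 ± 0.15 (adjusted p = 0.106, and 0.0224 with the replicate block). Proliferation genes had 16 of 22 higher and a median of 0.93 (18 adjusted over the list alone), including Rrm2 (1.79 ± 0.27) and Mcm5 (1.72 ± 0.25), both needed for DNA replication.

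Genes of detoxification and muscle went the other way. Xenobiotic metabolism had 13 of 21 members lower and a median of -0.75 (16 adjusted over the list alone), including the epoxide hydrolase Ephx1 (-1.24 ± 0.15), Aldh3a1 (-1.14 ± 0.19) and Aox3 (-1.02 ± 0.16). Heart and skeletal muscle markers had 6 of 20 lower and a median of -0.65 (14 adjusted over the list alone). This call was lost with an estimated correlation (adjusted p = 0.212). Lower medians passed camera for markers of type I alveolar cells (-0.31), ciliated cells (-0.39), endothelium (-0.32), fat (-0.27) and clock genes (-0.30), with 2, 0, 0, 1 and 2 members called lower. These calls were lost with an estimated correlation (adjusted p = 0.339, 0.312, 0.495, 0.468 and 0.558). The endothelial call was also lost without wild-type mock B (adjusted p = 0.0616) and the fat call without wild-type mock A (adjusted p = 0.0703). The clock call was lost without wild-type infected B (adjusted p = 0.0608) and without wild-type mock C, where the median was -0.11 (adjusted p = 0.356). Without wild-type mock B the median was -0.46. The clock score was 0.33 on mock C, -0.13 and -0.21 on mock A and B, and -0.32, -0.39 and -0.14 on the infected arrays. In the clock list the repressor Nr1d1 fell by 1.12 ± 0.20 while Bhlhe40 rose by 0.84 ± 0.16, a call lost without wild-type infected B (adjusted p = 0.0503). Fibroblast and matrix genes (median 0.20, 3 of 16 higher, led by Timp1 at 3.66 ± 0.37 and Tnc at 2.43 ± 0.31) and immediate early genes (median 0.46, 3 of 20 higher, such as Junb at 1.43 ± 0.23) were called upward. Both calls were lost with an estimated correlation (adjusted p = 0.502 and 0.243), and the fibroblast call was lost without wild-type mock C (adjusted p = 0.0808). Without wild-type infected B the immediate early median was 0.29. Sftpc (-0.19 ± 0.09) and Scgb1a1 (-0.21 ± 0.13), the marker transcripts of type II and club cells, did not pass (adjusted p = 0.298 and 0.418). The lists for type II, club and goblet, T and NK, B and plasma, alveolar macrophage, red cell, and thymus and lymph node markers and for Myd88 neighbours were not called; in the club and goblet list the median (-0.05) and the mean (0.24) differ in sign.

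Camera called 21 of 30 lists in wild type. With an estimated correlation 9 remained past the threshold, at adjusted p from 0.0370 to 0.0463: neutrophil markers, both chemokine lists, NF-kB targets, acute phase, both interferon lists, proliferation and xenobiotic metabolism. The p of each of the others is given above. With the replicate block 761 genes were higher and 641 lower. Without wild-type infected B 298 genes were higher and 94 lower, and the number lower was 150 and 179 without wild-type infected A and C and 137, 198 and 201 without wild-type mock A, B and C.

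In MyD88 knockout mice infection raised interferon-stimulated and proliferation genes, and most inflammatory genes that led in wild type did not pass. Rrm2, a subunit of ribonucleotide reductase, and Cxcl10 rose most (2.66 ± 0.27 and 2.66 ± 0.29), followed by the protease inhibitor Timp1 (2.61 ± 0.37), Ifit1 (2.54 ± 0.23) and the mitotic gene Birc5 (2.35 ± 0.29). In all, 185 genes were higher and 7 lower. Acod1 (0.19 ± 0.27), Ccl3 (0.20 ± 0.18), Cxcl2 (-0.12 ± 0.26), Cxcl1 (0.09 ± 0.20), Tnf (0.00 ± 0.14), Il1b (0.33 ± 0.25) and Il6 (0.69 ± 0.36) did not pass, with adjusted p from 0.473 to 0.996.

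Type I interferon-stimulated genes had 17 of 30 members higher in the knockout and a median of 1.16 (24 adjusted over the list alone), among them Ifit3 (2.23 ± 0.16), Oasl2 (2.10 ± 0.20) and the transcription factor Irf7 (2.06 ± 0.23). Proliferation genes had 16 of 22 higher and a median of 1.20 (20 adjusted over the list alone), with the topoisomerase Top2a at 2.22 ± 0.35, Mki67 at 2.19 ± 0.30 and the cyclin Ccna2 at 1.47 ± 0.18. Interferon-gamma-inducible genes had a median of 0.72, with 3 of 24 higher (13 adjusted over the list alone; adjusted p = 0.212 with an estimated correlation), such as Igtp (1.28 ± 0.21) and Irgm1 (1.12 ± 0.15). Cxcl9 (0.99 ± 0.27, adjusted p = 0.112) and Saa3 (1.40 ± 0.34, adjusted p = 0.0682) did not pass; Saa3 passed without knockout infected A or knockout mock A (lowest adjusted p = 0.0266). The squamous epithelial protein gene Sprr1a rose by 2.03 ± 0.18, and factor B, Cfb, by 1.47 ± 0.22. Lcn2 rose by 1.56 ± 0.28, a call lost without knockout infected A or B or knockout mock C (highest adjusted p = 0.0683). Tlr2 was at 0.72 ± 0.24, not called (adjusted p = 0.201) but called with the replicate block (adjusted p = 0.0198).

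Of the 14 lists called in the knockout, type I interferon-stimulated and proliferation genes remained past the threshold with an estimated correlation (adjusted p = 0.0373 and 0.0370). The upward lists that were lost had, with an estimated correlation, adjusted p = 0.184 for acute phase, 0.212 for interferon-gamma-inducible genes, 0.213 for MHC class I, 0.281 for complement, 0.358 for alveolar macrophage markers, 0.363 for chemokines for monocytes and lymphocytes, 0.421 for monocyte and macrophage markers and 0.498 for both fibroblast and immediate early genes. Downward, xenobiotic metabolism had a median of -0.38 with 2 of 21 lower (7 adjusted over the list alone), with adjusted p = 0.136 with an estimated correlation; endothelial markers and clock genes had adjusted p = 0.606 and 0.558. MHC class II was called with the replicate block (adjusted p = 0.0293) and not without it (adjusted p = 0.0712). Its score was -0.78 on knockout mock C, 0.19 and 0.24 on knockout mock A and B, and 0.37, 0.39 and 0.16 on knockout infected A, B and C. Calls were also lost when 1 array was left out. The call of chemokines for monocytes and lymphocytes was lost without knockout infected B (adjusted p = 0.0782). That of endothelial markers (median -0.17) was lost without knockout infected C, where the median turned to 0.03, or knockout mock B, where it was -0.01 (0.843 and 0.703). The same held for fibroblast genes without knockout infected A or B or knockout mock C (0.169, 0.111 and 0.238). It held for immediate early genes without knockout infected A or knockout mock A (0.0894 and 0.0754). Clock genes lost their call without knockout infected A or B or knockout mock C (0.0771, 0.0751 and 0.281). Their median was -0.22, and without these arrays -0.18, -0.09 and -0.07, while without knockout infected C or knockout mock A it was -0.37 each time. The clock score was 0.35 on knockout mock C and -0.22 and -0.11 on knockout mock A and B. Neutrophil-attracting chemokines (median -0.13, none of 10 called, adjusted p = 0.367), NF-kB targets (median 0.09, adjusted p = 0.125) and neutrophil markers (median 0.18, adjusted p = 0.164) were not called.

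Knockout infected C had a 3' to 5' log2 difference of 2.02 for the Gapdh controls and 2.14 for the actin controls, against -0.10 to 0.25 and 0.09 to 0.68 on the other 11 arrays. Without it 192 genes were higher and 5 lower. With the replicate block 387 genes were higher and 35 lower, and after cyclic loess the share of calls that were higher was 85.9% in place of 96.4% (171 higher and 28 lower). The number higher was 77 without knockout infected A, 97 and 95 without knockout mock B and C, and 51 without both knockout B arrays. Each of the 7 falls, such as Aox3 (-0.86 ± 0.16), lost its call when at least 1 of several single arrays was left out, and their number ranged from 1 to 10.

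Genes called in both genotypes numbered 134, all with the same sign: 129 higher and 5 lower, against 8.11 and 0.18 for independent lists of these sizes. The 2 infection effects share no arrays, but arrays of the same letter deviate together between the mock groups (r = 0.460, 0.396 and 0.771 for A, B and C), which independent lists leave out. In 100 simulated draws without effects, deviations were shared within a letter at the average correlation over letters, and genes were drawn independently. At most 0 genes were called in both genotypes. The mock groups correlated at 0.447 within a letter in these draws, below the values for A and C above. The draws may therefore understate what shared deviations give. Across all genes, which are not independent replicates, the effects correlated at Pearson r = 0.62 and Spearman rho = 0.46, against a mean r of 0.13 in these draws. Their covariance was 0.0668, against a mean of 0.00334 in the draws. With 1 array per group, it averaged 0.0783 over the 3 pairs of effects of the same letter and 0.0611 over the 6 pairs of different letters. Part of the overlap may come from deviations shared within a letter. With the replicate block 259 genes were called alike. The number was 78, 79 and 86 without knockout infected A, knockout mock B and knockout mock C, and 44 without both knockout B arrays. Of the 866 genes called in wild type, 790 had the same sign in the knockout at any p. In the knockout 58 genes were called that were not called in wild type, none of which passed the test of the difference.

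**Figure D2:**
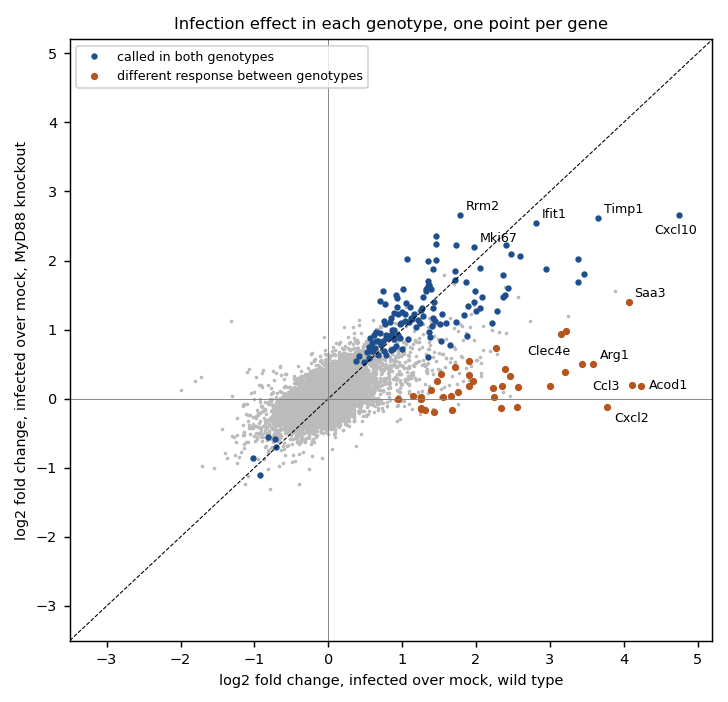
Log2 fold change of infected over mock in wild type (horizontal axis) and in the knockout (vertical axis) for 12393 genes. Blue points are the 134 genes called in both genotypes, orange points the 39 with a different response, grey points all others, and the dashed line marks equal effects; the orange points lie below the line, and Rrm2 lies above it.

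The response of 39 genes differed between the genotypes, and all 39 rose less in the knockout. The largest differences were those of Acod1 (-4.05 ± 0.39), Ccl3 (-3.91 ± 0.25), Cxcl2 (-3.89 ± 0.37), the arginase Arg1 (-3.09 ± 0.49), Clec4e (-2.93 ± 0.30), Il1rn (-2.82 ± 0.33), Ccl2 (-2.81 ± 0.44) and Ccl4 (-2.68 ± 0.33). All 39 were called higher in wild type, and none was called in the knockout. Further members were the dicarboxylate transporter gene Slc13a3 (-2.47 ± 0.21), Clec4d (-2.39 ± 0.19), C3ar1 (-2.18 ± 0.19), the lectin-like receptor Cd72 (-2.07 ± 0.23), the macrophage marker Adgre1 (-1.62 ± 0.20), Clec4a2 (-1.56 ± 0.21), and the cytokines Il1b (-2.13 ± 0.35) and Tnf (-1.25 ± 0.19). Cxcl9 (-2.23 ± 0.39), Ccl12 (-2.22 ± 0.36), Ccl7 (-1.96 ± 0.33), Cxcl1 (-1.66 ± 0.28) and C5ar1 (-1.38 ± 0.23) also passed. Il6 (-1.50 ± 0.51, adjusted p = 0.514, and 0.00523 without wild-type infected C), Nos2 (-0.69 ± 0.22, adjusted p = 0.463) and Lcn2 (-0.42 ± 0.39, adjusted p = 0.899) did not. Cxcl10 (-2.09 ± 0.40) had adjusted p = 0.0558, 0.0269 with the replicate block and 0.00523 without wild-type infected C.

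By list, the difference was largest for neutrophil-attracting chemokines and colony-stimulating factors, with a median of -1.06 and 4 of 10 members called (7 adjusted over the list alone). Neutrophil markers had a median of -0.84 with 2 of 22 called (9 adjusted over the list alone), proinflammatory cytokines and NF-kB targets -0.71 with 5 of 29 (14), and chemokines for monocytes and lymphocytes -0.61 with 4 of 17 (9), where the counts in parentheses are adjusted over the list alone. These 4 lists remained past the threshold with an estimated correlation (adjusted p = 0.0340 to 0.0373). The 2 neutrophil markers called were Clec4e and Clec4d. Other measured members, such as S100a8, Itgam and Lcn2, were not called, and neutrophil numbers are not part of these data. Monocyte and macrophage markers (median -0.83, 2 of 19 called, and 10 adjusted over the list alone), interferon-gamma-inducible genes (-0.71, 1 of 24, and 9), complement (-0.54, 2 of 13, and 4), type I interferon-stimulated genes (-0.43, none of 30, and 8), Toll-like receptor components (-0.36, none of 16, and 4) and acute phase genes (-0.27, 1 of 26, and 4) were called downward; with an estimated correlation their adjusted p = 0.0557, 0.0988, 0.197, 0.197, 0.0984 and 0.113. The complement median was -0.30 without knockout mock A and -0.31 without wild-type mock C. That of Toll-like receptor components was -0.23 without wild-type infected B or wild-type mock C, and that of acute phase genes -0.16 without wild-type infected B. Muscle markers (0.67), xenobiotic metabolism (0.38), type I alveolar markers (0.33), proliferation genes (0.21) and fat markers (0.16) were called upward, with adjusted p = 0.140, 0.213, 0.338, 0.669 and 0.502 with an estimated correlation. With the replicate block the proliferation and fat calls ended (adjusted p = 0.0529 and 0.0769). The type I alveolar call was lost without knockout infected A or knockout mock C (adjusted p = 0.0609 and 0.0514, with medians of 0.23 and 0.21). The fat call was lost without knockout infected C, wild-type infected B or C, or wild-type mock A or C (0.226, 0.0684, 0.0557, 0.0940 and 0.0613), with medians of 0.09, 0.22, 0.15, 0.20 and 0.16. It was kept with medians of 0.25, 0.27, 0.24 and 0.31 without knockout infected A or B, knockout mock C or wild-type mock B. The proliferation call was lost without knockout infected A or B, knockout mock B or C, wild-type infected A or B, or wild-type mock A or B (0.179, 0.146, 0.206, 0.195, 0.224, 0.0855, 0.120 and 0.247), with medians of 0.12, 0.29, 0.12, 0.12, 0.11, 0.22, 0.17 and 0.10. It was kept with medians of 0.33 and 0.31 without knockout mock A and wild-type mock C. The remaining 15 lists were not called.

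**Figure D3:**
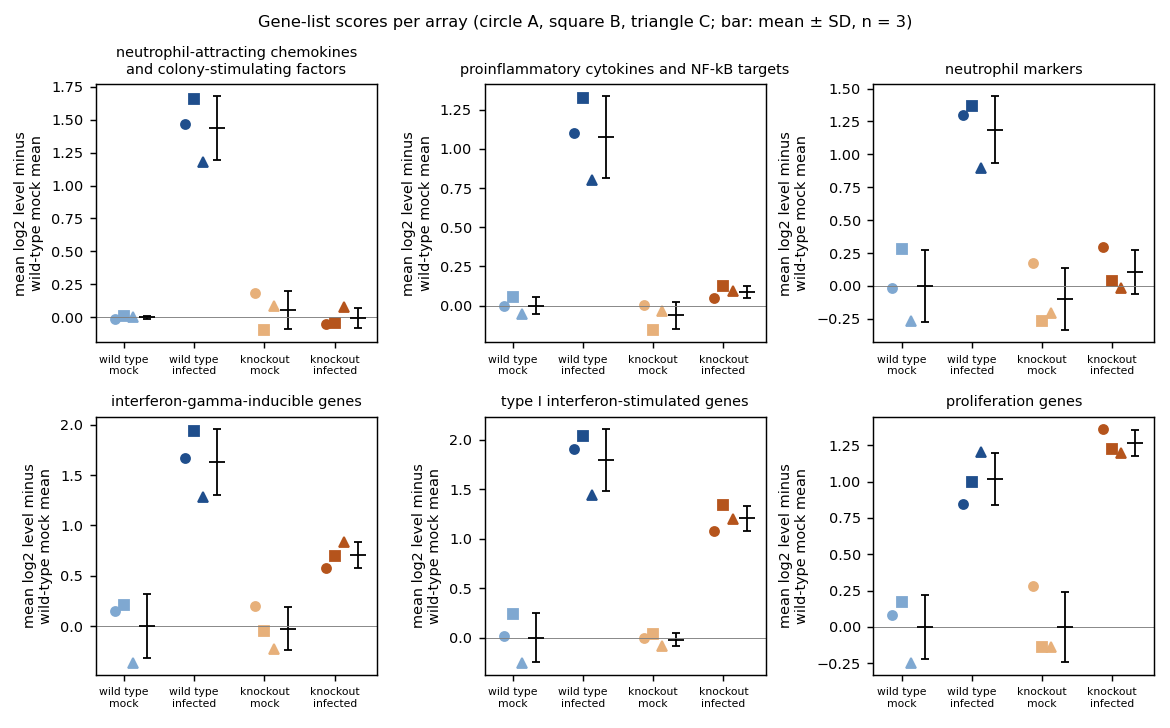
Mean log2 level of 6 gene lists on each array, minus the wild-type mock mean (vertical axis), in the 4 groups (horizontal axis). Circles, squares and triangles are replicates A, B and C, and bars give the mean ± SD of 3 arrays; chemokine, NF-kB target and neutrophil marker scores are separated from all other arrays in infected wild type only, while interferon and proliferation scores are higher in both infected groups.

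With the replicate block 58 genes had a negative and 2 a positive difference in response (Gask1b and Cox7a1, chosen after their values were seen). In that fit 38 of the 39 were called again, and Saa3 (-2.67 ± 0.48, adjusted p = 0.0382) was not (adjusted p = 0.0578). Positive differences numbered 9, 3 and 1 without knockout infected B, knockout mock B and wild-type mock C, and 50 with array weights. The number of negative differences was 18 without knockout infected A or knockout mock A, 19 without knockout mock C, 22 and 73 without wild-type infected A and C, and 21 without wild-type mock A. Acod1, Ccl3, Cxcl2, Clec4e, Il1rn and Ccl4 were called each time, while Arg1, Ccl2, Tnf, Il1b, Cxcl1, Cxcl9, Ccl12, Ccl7, C5ar1 and Saa3 each lost their call without at least 1 of these arrays (highest adjusted p from 0.0637 to 0.129). Where an A array was left out, the loss of an array cannot be told apart from the change in the sexes of its group.

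In mock-infected mice no gene differed between genotypes at an adjusted p below 0.05 in limma, while 473 had an unadjusted p below 0.05 and the smallest adjusted p was 0.342. That value belonged to Ighm, the immunoglobulin mu heavy chain (-3.02 ± 0.47, named after its value was seen), whose intensity was 11267, 4739 and 2399 in wild type and 792, 741 and 409 in the knockout. Tnf (0.05 ± 0.14), Il1b (-0.38 ± 0.25), Cxcl2 (0.16 ± 0.26), Cxcl10 (-0.04 ± 0.29), Saa3 (-0.06 ± 0.34), Tlr2 (-0.35 ± 0.24), Tlr4 (0.02 ± 0.15), Sftpc (0.06 ± 0.09) and Scgb1a1 (0.12 ± 0.13) lay within 2 standard errors of 0. The groups did not overlap for 11.8% of genes, where chance gives 10% for arrays independent of each other. Mock arrays of the same letter deviated together, so the share that chance gives here is not known.

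Camera called 8 lists, with no member called in any: muscle (median -0.35), alveolar macrophage (-0.26), B and plasma cell (-0.28), complement (-0.20), immediate early (-0.17), monocyte and macrophage (-0.16) and fat (-0.21) lower in the knockout, and club and goblet cell markers (0.12) higher. None of these 8 kept its call with an estimated correlation (adjusted p = 0.113 for club and goblet cell markers and 0.363 to 0.571 for the others), the fat call ended with the replicate block (adjusted p = 0.0702), and MHC class I was called with it (adjusted p = 0.0382, against 0.0734 without). Without knockout mock C 4 lists were called, and without wild-type mock A 5; without wild-type mock C 2 genes were called lower. Without knockout mock C the muscle, alveolar macrophage, B and plasma cell, complement, and monocyte and macrophage medians shrank to -0.17, -0.16, -0.11, -0.09 and -0.04 and the calls were lost (adjusted p = 0.0880, 0.303, 0.402, 0.183 and 0.238). Without wild-type mock A the complement and B and plasma cell medians shrank to -0.11 and -0.09 and the calls were lost (0.152 and 0.421). Without wild-type mock B the monocyte and macrophage and the B and plasma cell medians shrank to -0.03 and -0.10 and the calls were lost (0.576 and 0.253). Without wild-type mock C the immediate early and fat medians shrank to -0.05 and 0.00 and the calls were lost (0.243 and 0.114). Without knockout mock A the club and goblet and fat medians shrank to 0.08 and -0.13 and the calls were lost (0.0530 and 0.0825).

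The fat call (median -0.21) was also lost without wild-type mock A, knockout mock C, or knockout infected A or B (adjusted p = 0.313, 0.108, 0.0572 and 0.0578), with medians of -0.22, -0.35, -0.21 and -0.21. It was kept with medians of -0.13 and -0.34 without knockout mock B and wild-type mock B. Other medians lay further from 0 without an array, with the call kept. Without wild-type mock C they were -0.34 for complement, -0.34 for monocyte and macrophage markers and -0.50 for B and plasma cells, against -0.20, -0.16 and -0.28 with all arrays. Without knockout mock A they were -0.30 for complement and -0.41 for alveolar macrophages (-0.26 with all arrays), and without wild-type mock B -0.28 for immediate early genes (-0.17 with all arrays).

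In infected mice 211 genes were lower and 22 higher in the knockout than in wild type. The lowest relative to wild type were Ccl3 (-4.04 ± 0.18), Acod1 (-3.91 ± 0.27), Cxcl2 (-3.73 ± 0.26), Clec4e (-3.15 ± 0.21), the myeloid gene Slfn4 (-2.82 ± 0.44), Arg1 (-2.81 ± 0.35), Ccl2 (-2.77 ± 0.31) and Saa3 (-2.73 ± 0.34). These values compare the same infected arrays as the difference in response, so both sets of values are related. Cxcl10 (-2.13 ± 0.29), Il1b (-2.51 ± 0.25), Cxcl1 (-1.77 ± 0.20), Cd14 (-1.58 ± 0.22) and Tnf (-1.20 ± 0.14) were lower too, while Il6 (-1.37 ± 0.36, adjusted p = 0.0904, and 4.31e-04 without wild-type infected C), Ifng (-0.48 ± 0.17, adjusted p = 0.271) and S100a8 (-2.16 ± 0.85, adjusted p = 0.348) did not pass.

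Proinflammatory cytokines and NF-kB targets had 15 of 29 members lower and a median of -0.83 (22 adjusted over the list alone). Monocyte and macrophage markers had 10 of 19 lower and a median of -1.10 (13 adjusted over the list alone), such as Itgam (-2.27 ± 0.26), Fcgr1 (-2.08 ± 0.27) and Adgre1 (-1.81 ± 0.14). Neutrophil markers had 9 of 22 lower (13 adjusted over the list alone), among them Cd177 (-2.49 ± 0.35). Among those not called in limma were Ngp (0.17, adjusted p = 0.972), Camp (0.20, adjusted p = 0.930) and Ltf (-0.39, adjusted p = 0.528), chosen after their values were seen. These genes lie near Myd88 on its chromosome, so an effect of DNA carried along with the knockout allele cannot be told apart for them. The chemokine lists had 5 of 10 and 8 of 17 lower (7 and 9 adjusted over the list alone), including Cxcl13, which attracts B cells (-1.84 ± 0.22). Acute phase genes had 4 of 26 lower (7 adjusted over the list alone), among them Orm1 (-1.78 ± 0.23), and Toll-like receptor components 5 of 16 (6 adjusted over the list alone), among them Tlr1 (-1.58 ± 0.23). These 7 lists were the ones that remained past the threshold with an estimated correlation (adjusted p = 0.0340 to 0.0447).

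Interferon-gamma-inducible genes (8 of 24 lower), complement (7 of 13), type I interferon-stimulated genes (7 of 30), immediate early genes (1 of 20) and MHC class I (none of 12) were called downward with adjusted p = 0.0557, 0.0557, 0.113, 0.138 and 0.495 with an estimated correlation. Xenobiotic metabolism (median 0.42), type I alveolar (0.37), muscle (0.34), proliferation (0.31) and club and goblet markers (0.22) were called upward with adjusted p = 0.145, 0.213, 0.273, 0.502 and 0.184 with an estimated correlation. The club and goblet call was also lost without wild-type infected C (adjusted p = 0.0687) and the proliferation call without knockout infected A or wild-type infected A (0.0697 and 0.0509, with medians of 0.23 and 0.19). The xenobiotic metabolism median was 0.26 without knockout infected A. The genes higher in the knockout were led by Clec3b (1.80 ± 0.36), Bex1 (1.06 ± 0.23) and Sprr1a (1.02 ± 0.18), each of which lost its call without wild-type infected A. Itga9, a neighbour of Myd88, was higher by 0.78 ± 0.14 and also lost its call without wild-type infected A or knockout infected A.

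The number lower was 106 and 140 without knockout infected A and C, and 116 and 88 without wild-type infected A and B. The number higher was 3, 61 and 12 without knockout infected A, B and C, 1 and 2 without wild-type infected A and B, and 12 without wild-type mock A or B.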

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

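The test of a uniformly weaker response and the simulated draws without effects were chosen after the result was seen. So were the splits by replicate letter of the interaction, while the other splits of the arrays were not. The test of array quality had its prediction written before it was run. That prediction was made for the genes already called, so their number was known. Groups of 3 arrays were not tested for a single array far from its group.

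The effect of infection differed between the genotypes by a test of the difference itself for 39 genes (all of them lower in the knockout) and for 4 gene lists that also passed with an estimated correlation: neutrophil-attracting chemokines and colony-stimulating factors (median -1.06), neutrophil markers (-0.84), proinflammatory cytokines and NF-kB targets (-0.71) and chemokines for monocytes and lymphocytes (-0.61). Poor RNA on knockout infected C was tested as a reason for the weaker response. The median difference over the 39 genes was -1.72 with all arrays and -1.82 without that array. These genes had been called with that array included, so their median was unlikely to shrink, and it cannot decide the question. With that array left out 43 genes were called, all 39 among them, so these calls do not rest on it. A response scaled down alike for all genes was tested with the difference in response of the proliferation score minus that of the NF-kB target score. This was 1.17 with a standard error of 0.284, which argues against an equal scaling of these lists. Both lists were picked after their responses had been seen. The standard error allows neither for this pick nor for the pairing by letter, so the value describes these lists only. A part played by Myd88 in inducing these genes, fewer myeloid cells entering the lung, and a different bacterial load stay open and were not tested.

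With the genotype labels shuffled within the infected and within the mock arrays, 11 of 100 draws, the real one included, called as many genes as the real 39, and the highest other draw called 347. By this share chance is not excluded for the number of genes. However, 10 of these 11 were among the 11 draws that kept the real genotypes of the infected arrays, and so kept the difference between the genotypes in infected mice. Of the 89 draws that shuffled the infected arrays 1 reached 39, with 237. Why some draws called several times 39 genes was not tested. Of the 32 splits that part the arrays of every letter in both the infected and the mock arrays, 5, the real one included, called at least 39. All 5 were among the 8 that kept the infected genotypes (30 to 114 genes), and the highest of the 24 others was 0. With the replicate block 5 of 32 called at least the real 60, again among those 8 (51 to 193), and the highest of the 24 others was 0.

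For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real split called 866 genes for infection in wild type (highest other 0), 192 in the knockout (highest other 11), and 233 for genotype in infected mice (highest other 0), so that 1 of 10 splits reached the real count in each. For genotype in mock-infected mice the real split called 0 in limma (473 at an unadjusted p below 0.05; highest other 8), and 10 of 10 splits reached that. Among the 4 splits that, like the real one, part the arrays of every letter, the highest other count was 0 in each of these comparisons.

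Signals also appeared in data outside the comparisons. The RNA controls of knockout infected C had a 3' to 5' log2 difference of 2.02 for Gapdh and 2.14 for beta-actin, against highest values of 0.25 and 0.68 on the other arrays. Both knockout B arrays had high control signals: on knockout mock B and knockout infected B the 5' control of 18S RNA was at log2 13.84 and 13.58 (10.53 to 11.09 on the other 10 arrays), that of beta-actin at 13.74 and 13.98 (10.97 to 12.80), and the 3' control of BioB, a spiked-in hybridisation control, at 8.78 and 8.72 (7.02 to 7.87). No explanation was tested for these. Among the 2246 probe sets without a single gene symbol, 76 were called in wild-type infection (57 higher and 19 lower), and 12 higher and 1 lower in the knockout.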

How the results depend on the processing

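Leaving out both mock C arrays, both knockout B arrays, or knockout infected C with both mock C arrays was chosen after seeing the data: the mock C arrays stood apart from the other mock arrays, the 2 knockout B arrays shared a deviation from their group means (r = 0.538), and knockout infected C had high 3' to 5' control differences. In all, 28 alternatives were run. Across them 4861 values of named genes that had been called kept direction and call and 727 lost the call; of those not called 8175 stayed so and 475 passed. Of list calls 1698 were kept and 162 lost, and no called gene changed sign. Camera reversed the direction of no called list, but the median of endothelial markers in the knockout infection turned from -0.17 to 0.03 without knockout infected C. Where all 39 genes of the interaction were tested, all kept their sign. The causes of the shifts below were not tested, except that a fold minimum removes calls by construction and that the filter on dim genes tests fewer genes (17 of the 39).

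Leaving out 1 array at a time, the ranges were 298 to 614 higher and 94 to 434 lower for infection in wild type, 77 to 247 and 1 to 10 in the knockout, 0 to 9 and 18 to 73 for the interaction, 0 to 0 and 0 to 2 for genotype in mock-infected mice, and 1 to 61 and 88 to 242 in infected mice. Of genes called in wild type, 18 to 73 had a different response and 78 to 136 were called alike in the knockout, and the correlation of the effects was 0.49 to 0.67. Lists called numbered 20 to 23, 11 to 16, 13 to 20, 4 to 12 and 16 to 19 in the same order of comparisons. The interaction had 9, 3 and 1 genes higher without knockout infected B, knockout mock B and wild-type mock C; the correlation was 0.50, 0.55 and 0.49 without these. Genes called alike were 78, 79 and 86 without knockout infected A, knockout mock B and C. The number lower in the knockout infection was 1, 2 and 1 without knockout infected B, knockout mock B and C, 1, 2 and 2 without wild-type infected A, B and C, and 3 without wild-type mock A or B.

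With array weights, which ran from 0.302 for knockout infected C to 8.51 for wild-type mock A, 1293 genes were higher and 1697 lower in wild type, 3 lower in the knockout, 50 higher and 118 lower for the interaction, 2 and 3 for genotype in mock-infected mice, and 53 higher in infected mice; 162 wild-type genes had a different response, and the correlation was 0.49. The replicate block gave 641 lower in wild type, 387 higher and 35 lower in the knockout, 2 higher for the interaction, 44 higher for genotype in infected mice, 60 genes with a different response and 259 called alike. The random block (correlation 0.245) gave 661, 387 and 29, 6 higher and 77 lower for the interaction, 67, 82 and 259. Fitting only the groups compared gave 520 lower in wild type, and 100 higher and 0 lower in the knockout; it gives no value for the interaction.

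The filter on dim genes gave 340 higher in wild type, 15 lower for the interaction (15 with a different response), 117 lower in infected mice, a correlation of 0.71, and 9 lists in the knockout and 4 for genotype in mock-infected mice. A fold minimum left 258 and 31 in wild type, 89 and 1 in the knockout, 3 and 125 in infected mice and 68 called alike. Every probe set on its own gave 3 lower in the knockout and 2 higher in mock-infected mice, and cyclic loess 28 lower in the knockout. With an estimated correlation 9, 2, 4, 0 and 7 lists were called, in place of 21, 14, 15, 8 and 17.

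Without both mock C arrays there were 2 lower in the knockout, 19 lower for the interaction (19 with a different response), 2 lower in mock-infected and 40 higher in infected mice. Without both knockout B arrays there were 51 higher and 0 lower in the knockout, 9 higher for the interaction, 54 higher and 139 lower in infected mice, 44 called alike, and a correlation of 0.48. Without knockout infected C and both mock C arrays there were 2 higher and 23 lower for the interaction, 25 with a different response, 2 lower in mock-infected and 63 higher in infected mice, and a correlation of 0.54. For lists, the random block and the probe set as unit were not run. Where 1 array is left out, the 2 others of its group are assumed to vary like the other groups.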

Other observations

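The tests in this part were chosen after the result was seen. The test of glucocorticoid-inducible genes followed from genes seen to be raised on the mock C arrays. Its prediction was written before the listed genes were looked at.

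The mock C arrays of both genotypes stood apart from the mock A and B arrays. Of genes chosen after their values were seen, Fkbp5 was 2.82 (wild type) and 2.57 (knockout) log2 units above their mean, Tsc22d3 1.92 and 1.83, and Per1 2.09 and 1.75, while MHC class II genes had medians of -1.48 and -1.15. A list of 15 glucocorticoid-inducible genes, none of them looked at before, was written for a test; 13 were measured, and their median deviation was 0.39 averaged over the genotypes. The medians of 0.52 and 0.26 lay at the 100th and 99.8th percentiles of 10000 random lists matched on expression, with 12 and 10 of the 13 genes higher. The random lists were drawn gene by gene, so these percentiles do not allow for genes that vary together. The test also used the same mock C arrays on which the pattern had been seen. A candidate explanation is a glucocorticoid-type response in these 2 mice. Clock genes were also higher (medians 0.46 and 0.47), so time of day stays open.

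Less blood left in these lungs was tested against the same pattern. It would raise all other genes alike. The 9 raised genes lay at least 1.54 above the other mock arrays, with medians of 0.04 and 0.07 over all genes. Since these 9 were picked for their high values on the mock C arrays, this restates the pick and cannot decide the question. For lowered genes such as Alas2 (-2.11 and -2.88, chosen after its values were seen) less blood cannot be told apart from other causes. The fibroblast and matrix genes, which less blood would not lower, had a mean median of -0.31. In wild type, however, their median was -0.21 with a standard error of 0.222. Degraded RNA cannot be told apart from other causes either, since the 2 controls disagree. The highest Gapdh 3' to 5' log2 difference of the mock C arrays, 0.12, lay within the range of the other mock arrays. For beta-actin the mock C arrays had the highest values of the mock arrays, 0.62 and 0.68, against up to 0.58 on the others.

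Near Myd88 on chromosome 9, Itga9 differed between the genotypes by 0.78 in mock-infected and 0.78 in infected mice, Clasp2 by 0.65 and 0.79, and Clec3b by 1.23 and 1.80; the adjusted p was 0.599, 0.939 and 0.939 in mock-infected and 0.0128, 0.0451 and 0.0235 in infected mice. DNA of another strain carried along with the knockout allele may do this. The mean absolute t of the 105 measured genes among the nearest 100 on each side was 0.959, at percentile 93.5 among 186 windows, short of the 95 set for the test, so this cannot be told apart from chance here. In infected mice the window lay at percentile 88.6. The list of Myd88 neighbours was not called in mock-infected (median 0.02, adjusted p = 0.469) or infected mice (median 0.10, adjusted p = 0.120).

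Of 38 proteasome genes, a set picked after some were seen among the genes called in the knockout, 10 were called higher there and 2 in wild type, and the median log2 fold changes were 0.43 and 0.26. Since the set was picked from the calls, a Fisher p of 1.42e-10 against the other genes restates the pick and tests nothing. The difference in response was called for none of them in limma.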
